A study of Rattus norvegicus with 11 samples.

How the data were processed

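The samples were 11 one-colour Affymetrix arrays of rat adrenal tissue, 7 lesions of rats heterozygous for a Cdkn1b mutation and 4 normal glands of wild-type rats. Each is labelled as its own biological replicate, which is taken here to mean a different animal. Total RNA was amplified with a whole-transcript kit for small inputs and labelled with biotin, per the labels' protocols. The authors deposited log2 expression values per probe set, made with RMA in Affymetrix Expression Console 1.3.0.187 per the submitters' processing notes. RMA corrects the background, normalizes arrays to a common distribution and summarises the probes of a set. The summary level and options, and the genome build behind the probe design, are not given in the sources used here. The deposited log2 values ran from 2.10 to 13.5 with near-equal array medians (4.91 to 5.01), so they were not centred per gene and were used without further normalization. Scanner intensities were not used here, so signal over background and scan batches were not analysed here. Arrays give no read depth, and their number limits the precision. No array equalled another.

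Gene names came from the platform annotation supplied for these probe sets. Of 29214 probe sets, 15310 had 1 gene symbol, 323 had several and 13581 were unlisted and are unnamed here. Of the 15310, 15279 matched by gene ID a RefSeq gene table of assembly GRCr8, which changed 0 symbols. No coordinate from that table was used. The 14506 distinct symbols included 527 with more than 1 probe set, for which the probe set with the highest mean over all arrays stood for the gene. The plan was to leave array controls out of the tests, but the annotation used here does not mark them, so all 29214 probe sets were tested. Pnmt, Mki67, Xist and the Y-linked genes chosen for a check of the sex labels were named by no single-symbol probe set and were not analysed here.

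Differences were tested two-sided with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the log2 values, with Benjamini-Hochberg adjustment over all probe sets and calls at an adjusted p under 0.05. The main comparison fitted group alone over all 11 arrays. Age comparisons used a model of group by age class (21 to 24 months against 12 to 13 months), sex was tested with group in the model, and interactions in 4-cell models, so that all arrays shared 1 estimate of the spread. Confidence intervals are 95% intervals from the moderated fit. The 27 gene lists, the genes to be named and the alternatives were fixed before the data were examined. The lists were tested with camera (preset correlation 0.01) on 1 probe set per gene. Camera with an estimated correlation and fry were alternatives for the main comparison. Testing the lists in the age and sex comparisons, exact permutation of per-array list means, the Bmal1 covariate and 3 further lists (pituitary hormone, circadian clock and granulocyte genes) were added after the data were seen.

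The naming rule took Cdkn1b, then up to 8 genes per direction with the largest difference among those called with no overlap between groups, a fixed set of adrenal genes whatever their test, and up to 3 members per list with the largest difference, of which 2 were used. For age and sex it took up to 5 called genes per direction. Genes outside it are said to be named after their values were seen. Of genes with more than 1 probe set, the others of Klf4, Rrm2, Cs and Rps14 went in the same direction.

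The procedure was tested on simulated data with the means and spreads of the 29214 real probe sets and 200 changed ones. In the comparison of lesion and normal arrays it recovered 84 of 100 probe sets changed 2-fold and 98 of 100 changed 4-fold, with 17 of the unchanged called. For older against younger lesions it recovered 74 and 98, with 11 unchanged called, and for males against females 83 and 94, with 4 unchanged called. Camera called a simulated list shifted by 0.5 among 14506 genes and none of the other 26. The genes were drawn independently, so this does not test how camera with its preset correlation treats genes that vary together. The simulated spreads were those within group and age class, while the main and sex comparisons had no age in the model. Recovery in those comparisons may therefore be overstated. Alternatives were renewed quantile normalization, median centring, filters on dim probe sets, eBayes with trend and robust settings, array weights, 1 value per gene and covariates. Others were the replicate number as a block, subsets by age or sex, a stricter threshold and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.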

Results

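Gene expression was measured on one-colour Affymetrix arrays in 11 rat adrenal samples, 1 array per biological replicate, each taken to be a different animal. Lesions were taken from 7 rats heterozygous for a mutation of Cdkn1b, the gene of the cyclin-dependent kinase inhibitor p27Kip1. Normal adrenal glands were taken from 4 wild-type rats. In the rat strain that carries this mutation (MENX) neuroendocrine tumours arise in several glands. The lesions came from 3 animals of 21 to 23 months and 4 of 13 months (4 males and 3 females). The normal glands came from 2 animals of 24 months and 2 of 12 months (2 males and 2 females). Values are log2 expression per probe set after robust multi-array averaging by the authors, and 29214 probe sets were tested. Array medians lay between 4.91 and 5.01, and array pairs correlated at 0.960 to 0.992 across probe sets. The array format gives no read depth, and the number of arrays limits the precision.

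The comparison named by the series design set the lesions against the normal glands. Transcripts of the immediate early response, genes switched on within minutes of a stimulus to a cell, were much lower in lesions. Egr1, a zinc-finger transcription factor of this class (probe set 10800919), fell from 10.18 ± 0.43 in normal glands (SD, n = 4) to 7.29 ± 0.17 in lesions (SD, n = 7), a difference of -2.89 (SE 0.17, limma adjusted p = 2.33e-05). The orphan nuclear receptor Nr4a2 fell by 3.21 on the log2 scale (SE 0.32, adjusted p = 0.00293) and the zinc-finger factor Klf4 by 2.31 (SE 0.27, adjusted p = 0.00866). The AP-1 subunit Fos fell by 2.10 (SE 0.31, adjusted p = 0.0307), its partner Junb by 1.98 (SE 0.27, adjusted p = 0.0167) and the stress-induced factor Atf3 by 1.37 (SE 0.16, adjusted p = 0.00859). For each of these 6 genes all 7 lesions lay below all 4 normal glands.

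Of the 20 measured members of the immediate early list, 6 fell, 0 rose and 14 were not called. Adjusted over the list alone, 13 fell. Members that missed the threshold over all probe sets included Dusp1, a phosphatase that inactivates MAP kinases (difference -1.97, 95% CI -2.68 to -1.25, adjusted p = 0.0729) and the RNA-binding protein Zfp36 (-1.12, 95% CI -1.54 to -0.71, adjusted p = 0.0796). So did the nuclear receptors Nr4a1 (-1.88, 95% CI -2.79 to -0.97) and Nr4a3 (-1.80, 95% CI -2.73 to -0.87). Jund, Egr4 and Myc of the same list lay near 0, and these 7 members were named after their values were seen. The list as a whole was lower in lesions (camera adjusted p = 2.36e-18, and adjusted p = 0.000119 with an estimated correlation). Its mean over members was 6.52 ± 0.08 in lesions (SD, n = 7) and 7.63 ± 0.13 in normal glands (SD, n = 4), with no overlap (difference -1.11, two-sided exact permutation p = 0.00303, the smallest that the 330 splits allow, adjusted p = 0.0818 over the 27 lists).

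**Figure D1:**
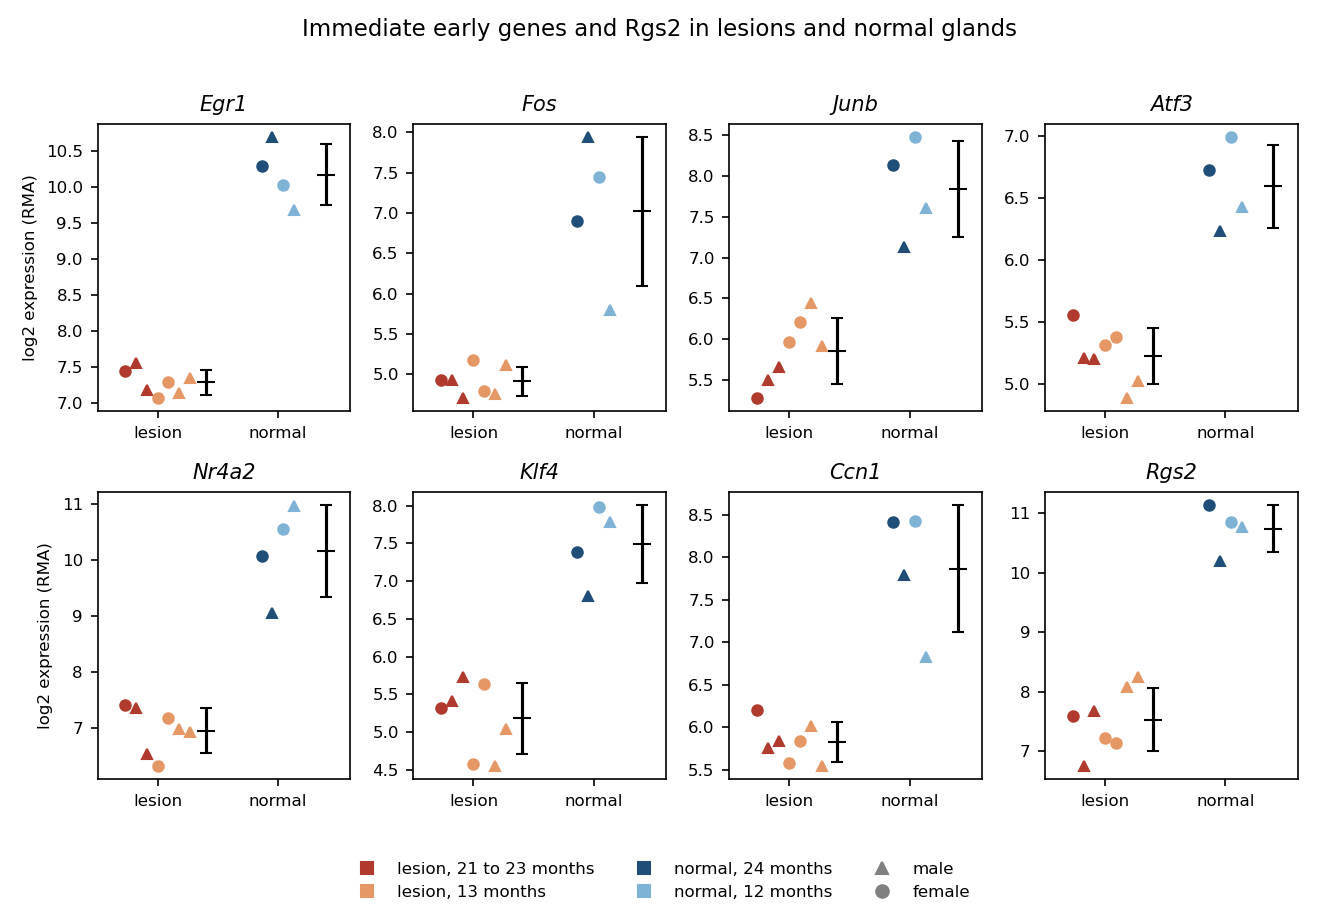
Log2 expression (vertical axis) of 8 genes that fell, on each array, by group (horizontal axis), with colour for age and shape for sex; bars are mean and SD of each group (n = 7 lesions, n = 4 normal glands). Every lesion lay below every normal gland for each gene, and for Egr1 the group means were 7.29 and 10.18.

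In all, 19 probe sets were called at an adjusted p under 0.05, 0 of them higher and 19 lower in lesions, and 17 of the 19 differed at least 2-fold. Among the other named genes that fell were Rgs2, which restrains signalling through G-protein-coupled receptors (by 3.21, SE 0.27, adjusted p = 0.000664), and Id3, an inhibitor of basic helix-loop-helix transcription factors (by 1.63, SE 0.12, adjusted p = 0.000292). The matricellular protein gene Ccn1 fell by 2.04 (SE 0.26, adjusted p = 0.0150) and the serum-inducible kinase gene Plk2 by 1.69 (SE 0.24, adjusted p = 0.0251). Outside the rule for naming genes, and named after their values were seen, were Id3, Atf3 and also Adamts1, Gadd45g, Grb14, Plekhf1, Klhl40, Kyat3, Zrsr2-ps1 and Hcar2, of which the last 8 fell by 1.47, 1.40, 1.38, 1.35, 1.22, 1.13, 0.82 and 0.80. The remaining called probe set had no gene name here. Without regard to the call, 203 probe sets had all lesions below all normal glands and 140 had all lesions above, where chance gives 88.5 in each direction. At an unadjusted p under 0.05 there were 2251 probe sets, 1107 higher and 1144 lower, against 1460.7 by chance. The count fell to 5 without normal replicate 3 and to 11 without lesion replicate 7. The count of at least 2-fold changes fell to 5, 10, 11 and 11 without normal replicate 3, lesion replicate 7, lesion replicate 3 and normal replicate 1. Without lesion replicate 1, whose profile stood apart from the rest, 7 probe sets were higher and 21 lower. Several of the genes that fell lost their call under many of 28 alternatives, with Fos called under 12, Junb under 17, Plk2 under 14, Grb14 under 13 and Kyat3 under 11.

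No gene rose by the test, and the nearest were named after their values were seen. The phosphodiesterase gene Pde10a stood at 8.05 ± 0.82 in lesions (SD, n = 7) and 5.76 ± 0.17 in normal glands (SD, n = 4), with no overlap (difference 2.30, 95% CI 1.48 to 3.12, adjusted p = 0.0724). Angptl4, an inhibitor of lipoprotein lipase, differed by 1.84 (95% CI 1.06 to 2.62, adjusted p = 0.171) and Scarb1, the receptor through which adrenal cells take up cholesterol from high-density lipoprotein, by 1.33 (95% CI 0.64 to 2.03, adjusted p = 0.258). All 3 were called without lesion replicate 1, and Pde10a under 8 of 28 alternatives.

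Neither the mutated gene nor the chosen markers of the gland itself were called, and several of these values depended on lesion replicate 1. Cdkn1b stood at 7.79 ± 0.43 in lesions (SD, n = 7) and 7.82 ± 0.16 in normal glands (SD, n = 4), a difference of -0.03 (95% CI -0.48 to 0.41), or -0.18 without lesion replicate 1. Where its probes lie relative to the mutation is not given in the sources used here, so this level does not check the genotype labels. Of the chromaffin genes, Th, the rate-limiting enzyme of catecholamine synthesis, differed by -0.01 (95% CI -0.38 to 0.37) and Ddc by -0.09 (95% CI -0.83 to 0.66). Dbh, which makes noradrenaline, differed by -0.05 (95% CI -0.37 to 0.26), Chga by -0.22 (95% CI -0.56 to 0.13) and Chgb by -0.15 (95% CI -0.34 to 0.04). Without lesion replicate 1 these 5 differences were -0.05, -0.31, -0.06, -0.12 and -0.13, none called. Of the cortical genes, Star, which carries cholesterol into mitochondria, differed by 0.07 (95% CI -0.23 to 0.38). Of the steroid hydroxylase genes, Cyp11a1 differed by -0.01 (95% CI -0.43 to 0.42), Cyp11b1 by 0.08 (95% CI -0.53 to 0.68) and Cyp21a1 by 0.38 (95% CI -0.33 to 1.08). Without lesion replicate 1 these 4 cortical differences were 0.18, 0.15, 0.29 and 0.62, none called, and the other 6 lesions (lowest 11.891) lay above every normal gland (highest 11.886) for Cyp21a1. The neuropeptide gene Npy differed by -0.61 (95% CI -1.35 to 0.13), Calca by 0.16 (95% CI -0.22 to 0.53), the receptor gene Ret by 0.52 (95% CI -0.72 to 1.76). The cell cycle inhibitor genes Cdkn2a and Cdkn2c differed by 0.93 (95% CI -0.30 to 2.17) and 0.06 (95% CI -0.16 to 0.28). Without lesion replicate 1 the differences were -0.36 for Npy, 0.25 for Calca, 0.06 for Ret, 0.47 for Cdkn2a and -0.00275 for Cdkn2c. Calca, at 3.51 to 4.69, lay below the median of every array, so its small difference says little. Th, Dbh, Chgb, Star and Cyp11a1 lay at 11.3 to 12.6, near the array maxima of 13.4 to 13.5. Whether differences are compressed at such levels was not analysed here. The transcription factor gene Tfap2b (-1.20, 95% CI -1.80 to -0.60, adjusted p = 0.258), the noradrenaline transporter gene Slc6a2 (-0.82, 95% CI -1.36 to -0.27) and the neurofilament gene Nefm (-0.95, 95% CI -1.54 to -0.36) were the members with the largest differences in the lists of sympathoadrenal, catecholamine and neuronal genes, and none was called.

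Of the 27 gene lists fixed before the data were examined, camera with its preset correlation called 8. Beside the immediate early list, 4 were lower and 3 higher in lesions, and for these 7 no member was called over all probe sets. The interferon response and antigen presentation list had a median difference of -0.21 (adjusted p = 0.00312, and adjusted p = 0.298 with an estimated correlation), led by the chemokine Cxcl10 (-1.89, 95% CI -2.61 to -1.18, adjusted p = 0.0847), with 3 members lower when adjusted over the list alone. The neuronal structure list had a median of -0.21 (adjusted p = 0.00852, and adjusted p = 0.653 with an estimated correlation). The fibroblast and extracellular matrix list had a median of -0.09 (adjusted p = 0.00762, and adjusted p = 0.105 with an estimated correlation), and the Schwann and sustentacular cell list one of -0.08 (adjusted p = 0.0278, and adjusted p = 0.298 with an estimated correlation). The cell division list was higher, with 30 of 32 measured members above 0, a median of 0.40 and none called when adjusted over the list alone (adjusted p = 5.67e-12, and adjusted p = 0.298 with an estimated correlation). Exact permutation of its per-array mean gave p = 0.0364 (adjusted p = 0.196 over the 27 lists). Cholesterol synthesis and uptake (median 0.33, adjusted p = 0.00486) and adipocyte markers (median 0.31, adjusted p = 0.00486) were also higher, each with an adjusted p = 0.653 with an estimated correlation. With an estimated correlation the immediate early list alone held its call. The other 7 also depended on the arrays and filters, though not equally. The neuronal median was 0.03 at 21 to 24 months and the cell division median 0.13 without the dimmer part of the probe sets, neither called. The Schwann and sustentacular cell list was called under 18 of 30 alternatives, with a median from -0.20 to 0.02. The fibroblast and extracellular matrix list was called under 27 of 30, also with fry (adjusted p = 0.00818). The cell division median was 0.12 at 12 to 13 months and 0.69 at 21 to 24 months, called at both.

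The other 19 lists were not called. Their medians were 0.07 for adrenal cortex steroidogenesis (0.22 and called without lesion replicate 1, and called under 4 of 30 alternatives), -0.06 for catecholamine synthesis, -0.12 for chromaffin granule genes, -0.04 for sympathoadrenal transcription factors, 0.05 for neuropeptides, -0.03 for RET and other receptor kinases, -0.09 for somatostatin, dopamine and nicotinic receptors and -0.11 for voltage-gated channels. They were 0.07 for cyclins and cyclin-dependent kinase inhibitors, -0.01 for hypoxia and glycolysis, -0.04 for the tricarboxylic acid cycle, 0.01 for WNT signalling (mean -0.01) and 0.02 for ribosomal proteins. Among markers of other cells, the medians were 0.09 for endothelium, -0.07 for pericytes and smooth muscle, 0.04 for macrophages, 0.11 for lymphocytes, 0.05 for blood cells and 0.02 for liver and kidney. The mean of the somatostatin, dopamine and nicotinic receptor list was 0.00321, opposite in sign to its median and to the direction of its test. For WNT signalling the test also pointed down, against the sign of the median. Adjusted over the list alone, 1 steroidogenesis gene was higher and 1 sympathoadrenal gene lower, and none in the other 17 lists differed.

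**Figure D2:**
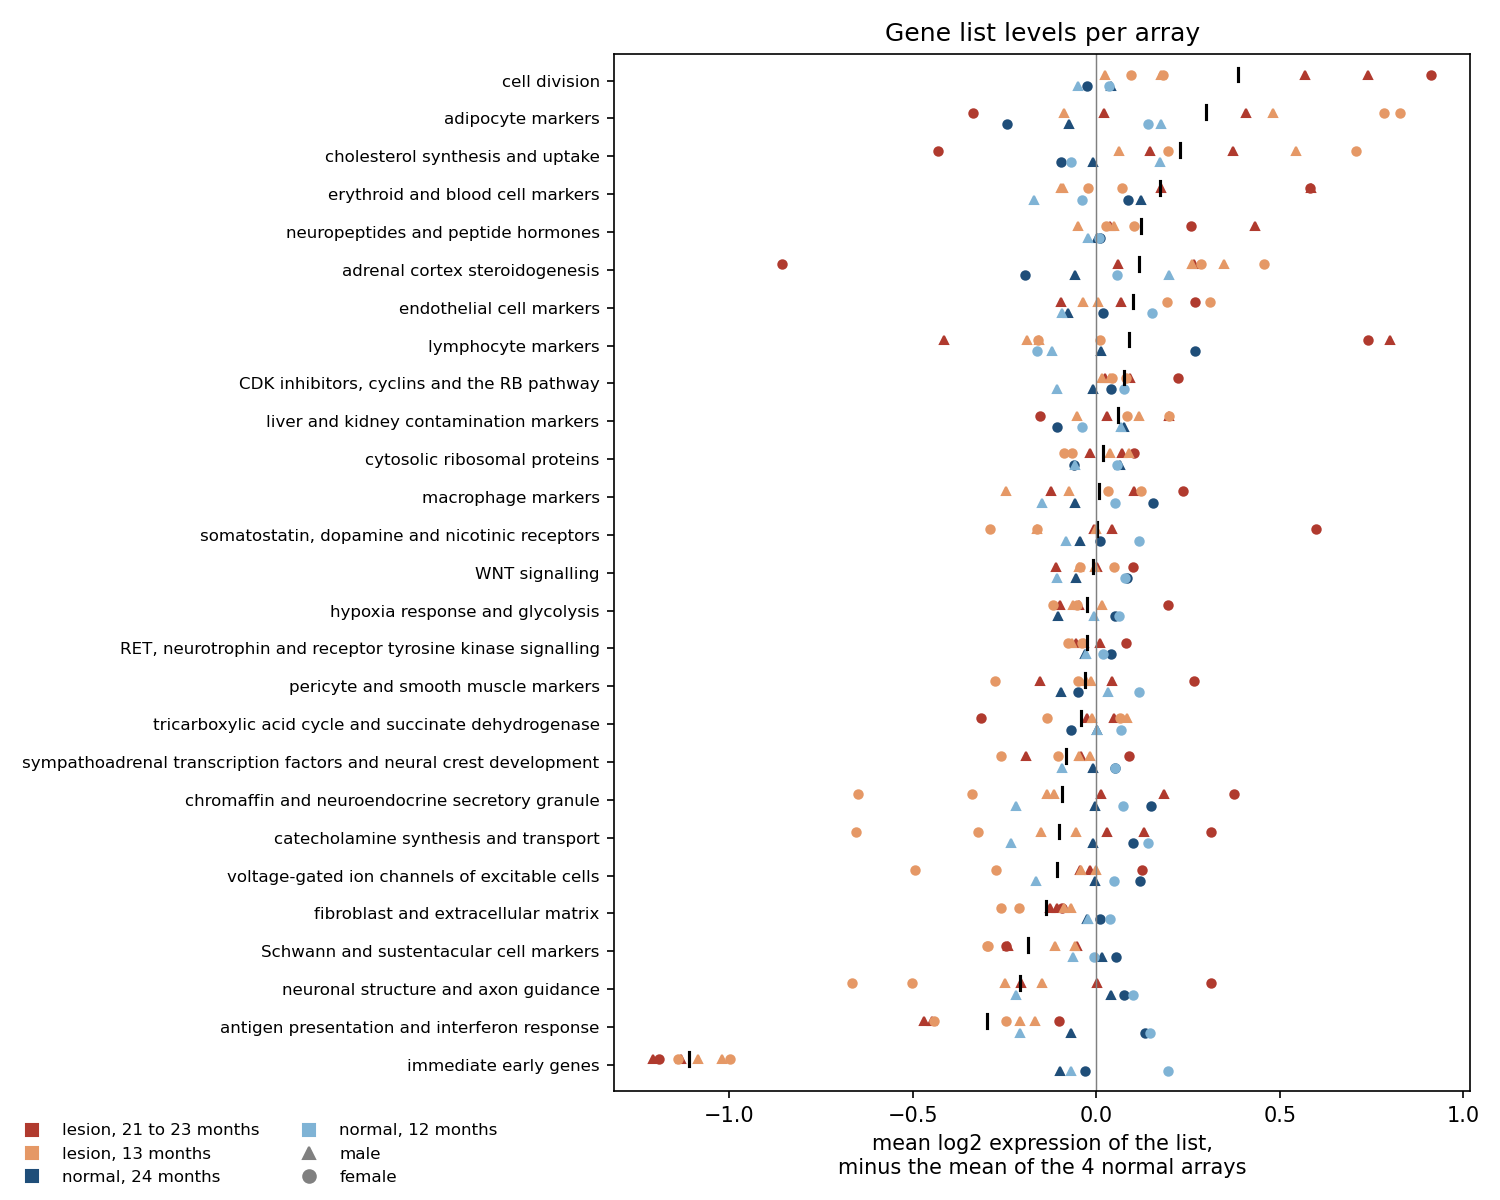
Mean log2 expression of each fixed gene list on each array, minus the mean of the 4 normal arrays (horizontal axis, log2 units), for the 27 lists (vertical axis); points are arrays, upper row lesions and lower row normal glands, and the black line is the lesion mean. Immediate early genes lay 1.11 lower on average in lesions, while for steroidogenesis 6 of 7 lesions lay above the mean of the normal glands and lesion 1 far below.

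Among lesions, age divided the samples by genes of cell division. Top2a, the DNA topoisomerase that untangles replicated chromosomes (probe set 10746976), stood between 6.53 and 6.90 in the 3 older lesions and between 4.25 and 4.46 in the 4 younger lesions. It was higher in older lesions by 2.33 (SE 0.15, limma adjusted p = 0.000852). Rrm2, the small subunit of ribonucleotide reductase, which makes deoxynucleotides for DNA synthesis, was higher by 1.21 in older lesions (SE 0.13, adjusted p = 0.0318). Prl, the gene of the hormone prolactin (probe set 10798310), was lower by 3.69 on the log2 scale in older lesions (older minus younger -3.69, SE 0.36, adjusted p = 0.018). Its log2 level was 7.05 to 8.95 in the 4 younger lesions, 4.23 to 4.61 in the 3 older lesions and 4.43 to 4.61 in the 4 normal glands. These were the 3 probe sets called, and 2805 had an unadjusted p under 0.05, against 1460.7 by chance.

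The cell division list was higher in older lesions, with 2 of 32 measured members called, 20 when adjusted over the list alone, and 31 above 0 (median 0.52, camera adjusted p = 2.07e-20, and adjusted p = 0.00823 with an estimated correlation). Exact permutation of its per-array mean gave p = 0.0286, the smallest that the 35 splits allow, and an adjusted p = 0.257 over the 27 lists. Members named after their values were seen were Ndc80, a kinetochore gene (1.43, SE 0.28, adjusted p = 0.247), Prc1, which bundles spindle microtubules (1.24, SE 0.28, adjusted p = 0.309), and cyclin B1, Ccnb1 (0.92, SE 0.14, adjusted p = 0.129). Camera called 8 further lists, none of which held with an estimated correlation. Chromaffin granule genes (median 0.39, adjusted p = 0.426 with an estimated correlation), catecholamine synthesis (0.27, adjusted p = 0.536), neuronal structure (0.39, adjusted p = 0.522), the receptor list (0.11, adjusted p = 0.426) and lymphocyte markers (0.18, adjusted p = 0.662) were higher in older lesions. Adrenal cortex steroidogenesis (-0.50, adjusted p = 0.549), cholesterol synthesis (-0.33, adjusted p = 0.662) and adipocyte markers (-0.35, adjusted p = 0.536) were lower. Without lesion replicate 1 the medians were -0.21 for steroidogenesis, -0.22 for adipocyte markers and -0.09, no longer called, for cholesterol synthesis. The lymphocyte median was 0.11 with array weights (not called), 0.37 without lesion replicate 2 and 1.13 without the dimmer part of the probe sets. That filter also gave 0.52 for the receptor list and 0.31 for cell division. The neutrophil and monocyte genes S100a8 and S100a9 differed by 2.50 (SE 0.49, adjusted p = 0.247) and 2.44 (SE 0.34, adjusted p = 0.129) and were not called. The blood cell list that holds them was not called either (median 0.17, camera adjusted p = 0.0549), with 2 members higher when adjusted over the list alone. That list was called under 8 of 23 alternatives, with a median from -0.01 to 0.33. The count of 3 depended on single arrays, and was 39 without lesion replicate 2, 7 without lesion replicate 3 and 6 without lesion replicate 6. It was 1 without lesion replicate 1, lesion replicate 4 or any of the 4 normal replicates. Top2a was called under all 22 alternatives that measured it, Prl under 15 of 23 and Rrm2 under 11 of 23.

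**Figure D3:**
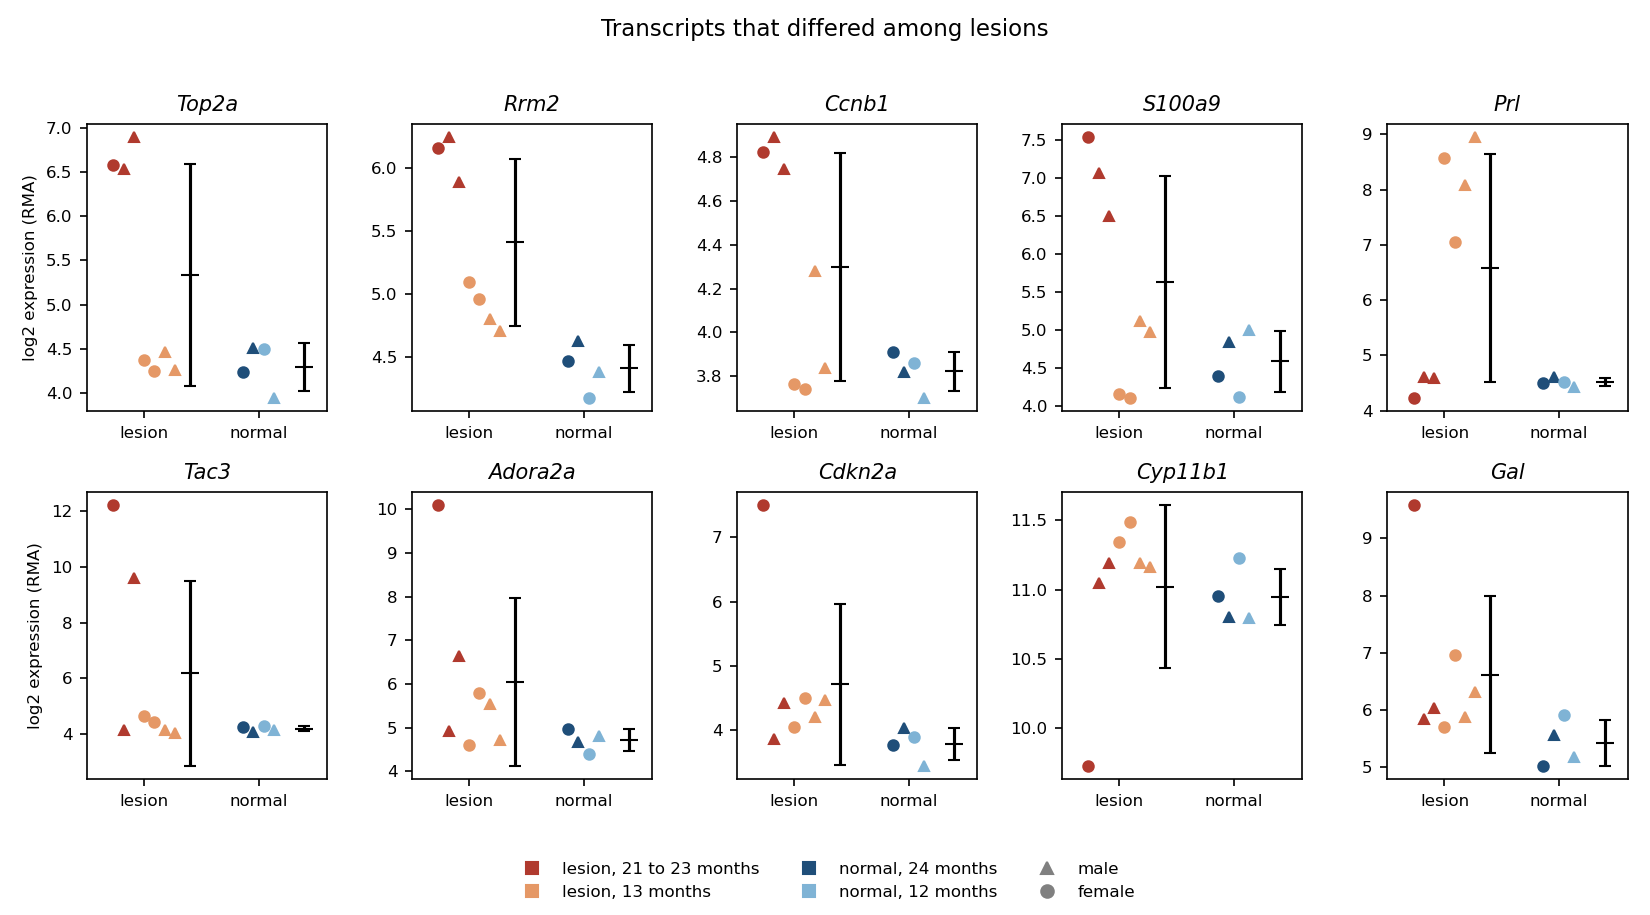
Log2 expression (vertical axis) of 10 genes on each array, by group (horizontal axis), with colour for age and shape for sex; bars are mean and SD of each group (n = 7 lesions, n = 4 normal glands). Top2a stood above 6.5 in the 3 older lesions alone, Prl was raised in the 4 younger lesions, and Tac3, Adora2a, Cdkn2a and Gal were highest in lesion 1.

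In normal glands no probe set was called between 24 and 12 months by limma (839 at an unadjusted p under 0.05, against 1460.7 by chance), and camera called none of the 27 lists, although up to 4 under alternatives. The test of whether the age difference differed between lesions and normal glands called no probe set (826 at an unadjusted p under 0.05, against 1460.7 by chance). The cell division list passed that test: its age difference was larger in lesions by a median of 0.57 (camera adjusted p = 1.75e-20, and adjusted p = 0.00814 with an estimated correlation). With 2 normal glands per age the precision is low. The circadian clock gene Bmal1, named after its values were seen, also divided the normal glands by age. It stood at 6.13 and 5.68 at 24 months and at 7.61 and 7.25 at 12 months. Age therefore cannot be told apart from the phase of the clock in normal glands, nor in the interaction that uses them. Simulated 2-fold and 4-fold changes were recovered for 46 and 91 of 100 probe sets in the normal comparison, and for 24 and 76 of 100 in the interaction.

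Between males and females, with group in the model, limma called no probe set (1154 at an unadjusted p under 0.05, 651 higher and 503 lower in males, against 1460.7 by chance). Xist and the Y-linked genes chosen for a check were not analysed here, so the sex labels are unchecked. Endothelial markers were lower in males as a list, with 15 of 16 members below 0 (median -0.21, camera adjusted p = 6.45e-09, and adjusted p = 0.00718 with an estimated correlation). Adjusted over the list alone 6 were lower, such as the vascular growth factor receptor genes Flt1 (-0.41, SE 0.11, adjusted p = 0.999) and Kdr (-0.42, SE 0.12, adjusted p = 0.999). Macrophage markers were also lower in males (median -0.27, camera adjusted p = 2.72e-07, and adjusted p = 0.0131 with an estimated correlation). Adjusted over the list alone 2 of 20 were lower, of which the lysosomal glycoprotein gene Cd68 differed by -0.71 (SE 0.10, adjusted p = 0.289). Flt1, Kdr and Cd68 were named after their values were seen. Camera also called steroidogenesis (median 0.17, adjusted p = 0.765 with an estimated correlation) and the tricarboxylic acid cycle (0.09, adjusted p = 0.693) as higher in males, and lymphocyte markers (-0.09, adjusted p = 0.765) as lower. Without lesion replicate 1, from a female, none of these 3 was called, and the steroidogenesis median turned to -0.07. The test of a sex difference in the lesion effect called no probe set (1927 at an unadjusted p under 0.05, against 1460.7 by chance). In it camera called 4 lists, none with an estimated correlation.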

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

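The tests on lymphocytes and on red cells and platelets, the count over all probe sets, and the tests of gene lists between ages and sexes were chosen only after the results were seen. Each named gene and list mean was examined for an array whose gap to its nearest neighbour took most of the range of its group (Dixon's test at 95%), which chance gives in about 1 in 20 groups. Of 266 groups of arrays 35 passed, 24 of them on lesion 1, a female of 23 months, but many of these genes were named for their values, so that count has no chance rate to be set against. Over all 29214 probe sets, 3690 passed in the lesions, with lesion 1 the most frequent array (1260, next 785), and 2680 in the normal glands, with normal replicate 4 the most frequent (990, next 623).

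Lesion 1 had high log2 levels of the adenosine receptor gene Adora2a (10.10), Gal (9.59), the somatostatin receptor gene Sstr1 (9.24), Hs3st2 (9.23), Cdkn1b (8.69), Cplx2 (8.56), Ret (8.32), Cdkn2c (8.20) and Cdkn2a (7.51). It had low levels of the cortical genes Star (11.78), Cyp11a1 (11.32), Cyp21a1 (10.41), Scarb1 (10.37), Cyp11b1 (9.72), the corticotropin receptor gene Mc2r (8.31), Dhcr7 (7.37) and the prolactin receptor gene Prlr (6.27), and of Npy (9.72), Angptl4 (5.70) and Serpina1 (4.19). The list means of steroidogenesis (7.48), hypoxia and glycolysis (8.26), cyclins and their inhibitors (6.93) and the receptor list (6.15) also stood apart there, the first below the other lesions and the others above. In 345 probe sets lesion 1 exceeded every other lesion by more than 1, and in 286 it lay below them by more than 1.

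Normal replicate 4 stood apart for Cdkn1b (7.59), Ret (4.89), Nefm (6.72) and Fcgr3a (6.24). Other single arrays that stood apart were lesion 4 for Dbh (11.59) and Id3 (7.27), lesion 3 for Adamts1 (6.14), lesion 2 for Zrsr2-ps1 (8.23), normal replicate 2 for Star (12.35), and normal replicate 1 for Pck1 (4.22) and Serpina1 (4.75).

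In the test of whether the age difference differed between lesions and normal glands, camera called 7 lists. The medians were 0.57 for cell division, 0.32 for neuronal structure, 0.31 for pericytes and smooth muscle, 0.29 for chromaffin granule genes, 0.22 for catecholamine synthesis, 0.22 for the receptor list and -0.31 for steroidogenesis. The last turned to 0.03, not called, without lesion replicate 1, where 4 lists were called, and without normal replicate 3 only cell division was called. With an estimated correlation cell division alone was called (adjusted p = 0.00814). In the test of whether the lesion effect differed between males and females, the medians of the 4 called lists were 0.42 for catecholamine synthesis, 0.33 for chromaffin granule genes, 0.39 for neuronal structure and 0.39 for voltage-gated channels, each with an adjusted p = 0.913 with an estimated correlation.

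The higher level of cell division genes in older lesions was not the work of lesion 1 alone: without it the list kept a median difference of 0.48 against 0.52 with it (camera adjusted p = 0.00976 with an estimated correlation). Lymphocytes could carry such transcripts in lesions 1 and 3, where the lymphocyte mean (5.59 and 5.65) exceeded every younger lesion in 2 of 2, but lesion 2, with a cell division mean of 5.18, had a lymphocyte mean of 4.43, below all younger lesions (4.66 to 4.86, SD 0.09). Granulocytes cannot be told apart from a change in the lesions: a 12-gene mean without S100a8 and S100a9 exceeded every younger lesion in 2 of 3, but lay below the median of every array and decides nothing, while S100a9 stood at 6.50 to 7.54 in older and 4.10 to 5.12 in younger lesions. The blood cell list was higher in all 3 older lesions (5.53 to 5.94 against 5.26 to 5.43), and its 9 red cell and platelet genes in 2 of 3, with lesion 2 lowest (5.59 against 5.66 to 6.05, SD 0.20), within the spread, so red cells and platelets cannot be told apart either. A difference in the lesions that goes with age stays open and was not tested.

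For the 3 probe sets called between older and younger lesions, the count of splits speaks against chance only narrowly and does not exclude it. Of the 35 splits 1, the real one, gave as many, and the highest other gave 2. That share, 0.0286, is the smallest that the 35 splits allow. The count is fragile besides, being 1 in the lesion arrays alone and 1 without any of 6 of the arrays. Chance cannot be excluded for the 9 lists called there, which 14 of the 35 splits reached, with 12 in the highest other split, nor for the 5 lists called between males and females, which 50 of 100 drawn splits reached (highest other 12). For the 0 probe sets called between males and females the splits decide nothing, since all 100 must reach 0 (highest other 2).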

How the results depend on the processing

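The Bmal1 covariate was chosen after the data were seen. Under quantile normalization, median centring, the filter on the dimmest 25% of probe sets, both eBayes settings, 1 probe set per gene and the mean of a gene's probe sets, every count for probe sets and for the lists of the main comparison stayed within 1.5 times the reported one. The 19 called between lesion and normal became 30 (2 higher, 28 lower) without the dimmer part of the probe sets, which leaves fewer tests, 31 (3 higher, 28 lower) with array weights and 29 (6 higher, 23 lower) with sex and age class as covariates. The 17 with at least 2-fold change became 26 without the dimmer part and 26 with array weights. With fewer arrays the counts fell, to 5 and 5 in animals of 12 to 13 months, and to 0 and 0 at 21 to 24 months, in males and in females. At an adjusted p under 0.01 both were 9. The 8 lists called became 3 at 21 to 24 months and 3 in males, 1 with an estimated correlation and 2 with fry. The 3 probe sets called between older and younger lesions became 1 in the lesion arrays alone. With Bmal1 as a covariate 21 probe sets were called in the main comparison and 2 in the older against younger lesions. Apart from fewer tests or arrays, the cause was not tested.

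With the replicate number as a block, 3 probe sets were called, all with at least 2-fold change. The block leaves little to estimate the spread from, so lost precision cannot be told apart from an effect of the numbers. Same-numbered arrays deviated together at correlations of 0.18, 0.15, 0.07 and 0.21. Numbers 3 and 4 each join animals of different sex, and the numbers were not taken as pairs. Even so, each of lesions 1 to 4 correlated best with the normal gland of its own number, a hint from the data and not from the design.

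Leaving out 1 array at a time gave 5 to 28 probe sets called in the main comparison, 5 to 25 with at least 2-fold change and 7 to 9 lists. For older against younger lesions it gave 1 to 39, for normal glands by age 0 to 1, for the age interaction 0 to 1, for sex 0 to 0 and for the sex interaction 0 to 1. A normal gland left alone in its age or sex class was assumed to vary like the other arrays. Leaving out 1 array gave 0 to 4 lists called between normal glands by age, 7 to 12 between older and younger lesions, 1 to 9 in the age interaction, 3 to 7 by sex and 0 to 8 in the sex interaction. Between normal glands 3 lists were also called with the filter on the dimmest 25%, both eBayes settings and array weights. Steroidogenesis changed direction without lesion 1. Over all alternatives its median ranged from -0.46 to 0.0315 in the age interaction and from -0.0746 to 0.273 by sex. By sex it was 0.25 without lesion replicate 4. In neither comparison was the list called where the sign changed. The immediate early list was called under all 30 alternatives (median -1.37 to -0.89), and Egr1 under 25 of 28 (difference -3.10 to -2.65, adjusted p 6.39e-06 to 0.239). Among the named genes that fell, the fewest calls were 11 of 28 for Kyat3 and 12 of 28 for Fos. Signal over background was not analysed here, so levels near the floor of the arrays have no stated bound.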

Other observations

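The tests on the clock gene Bmal1, on collection and on pituitary genes were chosen only after the results were seen, and the genes of this paragraph were named after their values were seen. Lesions differed in the hormones and immune transcripts they carried. Tac3, which encodes neurokinin B, had log2 levels of 12.23 in lesion 1 and 9.61 in lesion 3, against 4.05 to 4.64 in the other 5 lesions and 4.09 to 4.30 in normal glands. The mitochondrial subunit gene Cox4i2 (11.64 and 9.08) and the vesicular monoamine transporter gene Slc18a2 (9.54 and 7.90) were also highest in these lesions. Lesion 3 had the highest levels of the cytotoxic cell genes Gzma (9.05) and Klrd1 (6.66). Clock genes varied within both groups: Bmal1 stood at 5.68 to 6.13 in lesions 6 and 7 and normal replicates 1 and 2, and at 7.25 to 7.67 on the other 7 arrays, while Dbp stood at 9.12 to 9.73 and 7.60 to 8.40. Normal replicates 1 and 2 were the 24-month glands, so among normal glands this division coincided with age. Lesions 6 and 7 were the males of 13 months, so among the younger lesions it coincided with sex.

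The counts of called probe sets, which include 6 members of the immediate early list, were set against arbitrary divisions of the arrays. In 100 of the 330 splits of the 11 arrays into 7 and 4, 1 split, the real one, gave as many as 19 called probe sets (highest other 1), and 1 gave as many as 17 with at least 2-fold change (highest other 0). This speaks against chance for both counts, at the smallest share that 100 splits allow. For the immediate early mean itself, exact permutation over the 330 splits gave p = 0.00303 (adjusted p = 0.0818 over the 27 lists). Chance cannot be excluded for the 8 lists called, which 33 of the 100 splits reached, with 14 in the highest other.

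A different share of cell types in the samples is 1 explanation that could lower the immediate early genes. With each of 10 cell type scores added in turn, the difference of -1.11 stayed at -1.08 or beyond (95% CI -1.23 to -0.93 with blood cell markers added), and the interval nearest to 0, with fibroblast markers, was -1.32 to -0.84. This argues against a shift in any 1 of these cell types as the whole cause. With Bmal1 added it was -1.11 (95% CI -1.27 to -0.96), so the Bmal1 level did not account for it. This does not settle the phase of the clock, because Bmal1 hardly differed between the groups (0.26, limma adjusted p = 0.942). Cry1, named after its values were seen, stood at 5.21 to 5.90 in lesions and 4.68 to 5.10 in normal glands. The other measured genes of the clock list overlapped between the groups. Handling or stress at collection that differed between the groups may give the same pattern, since these genes respond within minutes, and it cannot be told apart from the lesion itself, because the labels used here give no record of collection. The gap of at least 0.93 between normal glands and lesions in each age class decides nothing on this, as either would give it. A lower level in lesion cells stays open beside these. So does an effect of the genotype, which cannot be told apart from the lesion. Every lesion came from a heterozygous rat and every normal gland from a wild-type rat.

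The prolactin transcript of the younger lesions may come from RNA or cells of pituitary origin, since Prl is a major transcript of that gland, but the values do not decide it. Of 7 other pituitary hormone and factor genes, 2 were higher in all 4 younger lesions than on the 7 other arrays, Gh1 (4.39 against 3.53 on average) and Cga (4.86 against 3.99). Chance gives this for a gene at a share of 0.00303, and the test took 2 such genes as a sign of pituitary material. On average both lay below the median of every array, though Cga stood at 5.24 and 5.14 in lesions 4 and 6. Levels this low neither carry nor exclude the explanation. Pomc, Lhb, Fshb, Tshb and Pou1f1 did not separate. Cross-hybridisation with relatives is not supported, as 0 of 21 other prolactin family probe sets were higher in these lesions by more than 1 (largest mean difference 0.23). Pituitary material cannot be told apart from expression in the lesions themselves, which was not tested.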
